A study of Homo sapiens with 8 samples.

How the data were processed

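The series compares m6A immunoprecipitation (IP) and input libraries of HCT116 cells with a non-targeting hairpin or a hairpin against ALKBH5, with 2 libraries in each of the 4 groups. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that the replicates came from separate cultures. The labels' protocols name more than 1 anti-m6A antibody, fragment size and sequencing platform, and which applied to these libraries is not given in the sources used here.

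Reads were processed by the authors. The submitters' processing notes name BWA 0.7.12, HOMER 4.9.1 and the build GRCh38, with no role or order. The program that called and compared the peaks is not given in the sources used here. The file analysed is 1 list of peaks for the whole series, with exon blocks, gene identifier and symbol. The authors' p-value of each peak is, per the file headers, given as a score and as its logarithm. The authors' fold enrichment is a linear ratio, read as IP over input per the file headers. The deposited log2 fold compares the arms, with its p and false discovery rate (FDR) as log10 values, per the file headers, and which arm is the numerator is not stated. Whether replicate spread entered that p is not given in the sources used here. Its log10 value reached -434 at log2 folds of 0.78 for MT-CO2 and 0.53 for MT-ATP6, with 2 libraries per group. Calls are therefore not read as reproducible between replicates. Coordinates are 1-based on GRCh38.

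The deposited FDR was checked by adjusting the deposited p over all 22626 peaks with the Benjamini-Hochberg method. It agreed within 0.02 on the log10 scale for 22469 of 22620 peaks whose p could be computed. The deposited p had a maximum of 0.773 and a median of 0.565 among 1009 peaks with a log2 fold within 0.05 of 0, where a two-sided p would approach 1. That median fell from 0.764 in the least to 0.495 in the most significant of 5 classes of peak p, and 5783 peaks in all had a p over 0.5. The kind of p is not given in the sources used here, but these values argue against a two-sided one. The deposited values were kept for the main counts, and p doubled (up to 1) and adjusted again was added as an alternative.

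Peaks past an FDR of 0.05 are called. The plan named both an adjusted p and the authors' own p of 0.05, and the unadjusted p gave 4493 peaks. The planned tests across libraries (transcript level, enrichment within each arm, the interaction, the relation of m6A to expression and the peak sets of each arm) need values per library and were not run. Motif counts need a genome sequence, which was not used here. Named genes followed a rule fixed before the data were examined. It takes the 10 largest positive and 10 largest negative folds among called peaks (1 peak per gene, unnamed loci and pseudogenes passed over), a fixed set of m6A genes with RAB5A, FOXO3, AXIN2 and MYC, and up to 4 called members of each gene list. Other genes named (AHNAK2, MPRIP, EPPK1, RPL15 and those opening the other observations) were chosen after their values were seen. Some genes that the rule takes are not reported here.

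Of 22 gene lists fixed before the data were examined, 17 had at least 5 genes with a peak and were tested. Genes with a positive (or negative) peak were counted among list members and among the other genes with a peak, with Fisher's exact test, two-sided, and Benjamini-Hochberg adjustment over 34 tests. Genes are not independent replicates, and these tests compare genes within 1 table, not conditions across libraries. Random lists (10000 draws) were matched on the number of peaks (4 classes) and on 5 classes each of the best peak's p and of enrichment, which stand in for abundance and were not a measure of it.

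Positions use the gene table of the GRCh38.p14 RefSeq annotation, matched by symbol. By symbol or synonym (296 peaks) 21133 peaks matched, and 20778 (91.8%) also lay within that gene. Peaks of different genes that share at least 1 base, on either strand, were merged into 20732 loci, keeping the peak with the smallest p of the difference. Such peaks numbered 3555. Merging the 384 peaks that overlap another peak of the same gene as well left 20560 loci. Their log2 folds correlated across 1143 pairs on opposite strands (Pearson r = 0.77, Spearman rho = 0.76), so both genes of such a pair are uncertain.

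To recentre the folds, the median log2 fold of all peaks (0.14) was subtracted and calls were made again. A standard error was taken from the fold and p, read as one-sided by assumption, where p was under 0.3 (11573 peaks). Elsewhere it was predicted from peak p, enrichment and length (held-out R2 of 0.90 for its logarithm). The held-out peaks also had a p under 0.3. That R2 therefore does not show how well the prediction holds for the 11053 peaks that were given it. With no shift this returned 1867 calls. A first version that read p as two-sided gave 1027 positive and 1793 negative calls (36.4% positive). It was dropped after its result was seen, because it gives peaks with folds near 0 a standard error near 0. The method was tested on simulated data for 22626 peaks with 200 changed by 2 on the log2 scale in equal numbers of either sign. In all simulated runs the changed peaks came from those with a standard error below the median. The simulated p was one-sided by construction, so the reading of the deposited p was not tested. With a simulated shift of 0.15, 72.7% of calls were positive before recentring and 51.0% after, and 65.5% of the changed peaks were recovered. Of the calls before recentring, 114 were of unchanged peaks. Calls were far fewer than the 1862 of the data, so the 72.7% cannot be set against the share in the data. With no simulated shift and 2000 changed peaks, 70% of them positive, 68.0% of calls were positive before and 66.7% after. Only 0.036 was subtracted there, against 0.14 in the data. Changed peaks moved by 2, where called peaks of the data had a median absolute log2 fold of 1.12. That run therefore does not show what subtracting 0.14 does to an excess among smaller folds. Of 2000 list tests on random lists, 2.4% had a p under 0.05.

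Shares have exact (Clopper-Pearson) 95% intervals, which cover counting error over peaks only. Alternatives fixed before the data were examined were an FDR of 0.01, an absolute log2 fold of at least 1, counting genes, the edges of peaks, the more significant peaks and 1 peak per gene. Calculations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.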

Results

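HCT116 cells, a human colorectal cancer line, carried either a non-targeting short hairpin RNA (shNC) or a hairpin against ALKBH5 (shALKBH5). ALKBH5 is a demethylase that removes N6-methyladenosine (m6A) from RNA. Poly(A) RNA was fragmented, and fragments bound by an antibody against m6A (the IP) were sequenced beside unselected fragments (the input). The series holds 8 libraries in 4 groups, with 2 libraries per group. The series' design text gives the purpose as describing which m6A sites depend on ALKBH5 and where they lie. The measurements analysed here are 1 list of 22626 m6A peaks, with the authors' own comparison of the arms. Values per library were not analysed here, so no value below has a replicate error, and the depth of the libraries is unknown.

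m6A peaks were found on 12009 genes by identifier, of which 10861 symbols are named. Most were on protein-coding genes (19552 peaks), and 756 were on long non-coding RNAs. Of the genes, 6197 (51.6%) had 1 peak and 534 had at least 5. The giant scaffold protein gene AHNAK2 had 23 listed peaks, which are 20 once overlapping ones are merged, MPRIP had 16, and the epithelial plakin gene EPPK1 had 14, which merge to 7. Enrichment of IP over input in the authors' deposited table had a median of 10.1-fold, with quartiles of 4.96 and 16.3. The median exonic length of a peak was 300 bases, and 6883 peaks (30.4%) spanned more than 1 exon block.

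ALKBH5 itself carried 3 peaks, and none passed the authors' false discovery rate (FDR) of 0.05. The authors' deposited table gives them log2 folds of -1.43, -0.93 and -1.25 between the arms, with FDRs of 0.40, 0.46 and 0.33. These lie on chromosome 17 (GRCh38) at 18184086 to 18184622, 18208258 to 18208466 and 18209597 to 18209924. Whether these folds are corrected for the level of the transcript is not given in the sources used here. The level of ALKBH5 itself was not analysed, so the knockdown was not checked here.

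The main comparison asks which peaks differed between shALKBH5 and shNC cells in the authors' comparison. Whether any of its folds is corrected for transcript level is not given in the sources used here. A called peak, here and in the gene lists below, may reflect m6A, transcript level or both, which cannot be told apart here. Of all peaks in the authors' deposited table, 1862 on 1644 genes passed an FDR of 0.05, 1298 with a positive and 564 with a negative log2 fold. Thus 69.7% of called peaks had a positive fold (exact binomial 95% interval 67.6 to 71.8). Which arm is the numerator of the fold is not given in the sources used here, so folds are called positive or negative, and neither sign is read as a gain or a loss in the knockdown. The median log2 fold of all 22626 peaks was 0.14. After that shift was subtracted, 934 peaks were called positive and 827 negative, a share of 53.04% positive (exact binomial 95% interval 50.7 to 55.4, and 48.0 to 58.5 with chromosomes resampled). The size of the excess of positive folds thus depends on where the folds are centred. With chromosomes resampled, so does whether the interval includes an equal split. Among peaks at least 1 from that median on the log2 scale, 60.7% of the first calls and 50.3% of the calls made again were positive. The deposited p never exceeded 0.773, and whether it is one-sided or two-sided is not given in the sources used here. Its median was 0.565 among 1009 peaks with a log2 fold within 0.05 of 0, where a two-sided p would approach 1. That argues against a two-sided p, so the main counts may be too large. With p doubled, as a one-sided p would require, 1035 positive and 403 negative peaks were called.

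Genes with the largest positive folds included PGAP2, which acts in the maturation of GPI-anchored proteins, and STK4, a kinase of the Hippo pathway. The authors' deposited table gives log2 folds of 4.82 for PGAP2 (FDR 7.6e-08), 4.60 for OSTF1 (FDR 0.0078), 4.44 for STK4 (FDR 0.0079), 4.27 for TMEM81 (FDR 0.0016) and 4.14 for TRIM4 (FDR 5.9e-06). COMTD1 stood at 4.07 in the authors' deposited table, the cilium transcription factor gene RFX3 at 4.06, the apoptosis inhibitor gene BIRC6 at 4.03, the telomerase assembly gene NAF1 at 4.0 and KLF3 at 3.90. The PGAP2 peak covered positions 3825715 to 3825983 of chromosome 11, with its centre 522 bases from the annotated 3′ end. The largest negative folds fell on TBC1D16, which encodes a RAB GTPase-activating protein, and on FNIP2, a partner of folliculin. Their log2 folds in the authors' deposited table were -5.12 (FDR 2.3e-05) and -4.85 (FDR 0.038). UBTF, a transcription factor gene of ribosomal DNA, stood at -4.58 and SGO2, a protector of centromeric cohesion, at -4.23 in the authors' deposited table. EPM2AIP1 stood at -4.27 in the authors' deposited table, UBN1 at -4.19 and the epithelial transcription factor gene GRHL2 at -4.02. NDUFB9 and MTSS1, at -4.31 and -4.28 in the authors' deposited table, overlap on opposite strands of chromosome 8 near position 124553009 and are listed for the same locus. With p doubled, COMTD1, KLF3, FNIP2 and UBTF no longer passed. Some of these peaks were themselves weak. In the authors' deposited table, the log10 p of the peak was -3.65 for OSTF1, -3.62 for STK4, -3.74 for KLF3 and -2.53 for FNIP2. It was -14.6 for NAF1, -15.6 for TBC1D16 and -21.5 for EPM2AIP1. Read counts behind these folds were not analysed here.

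**Figure D1:**
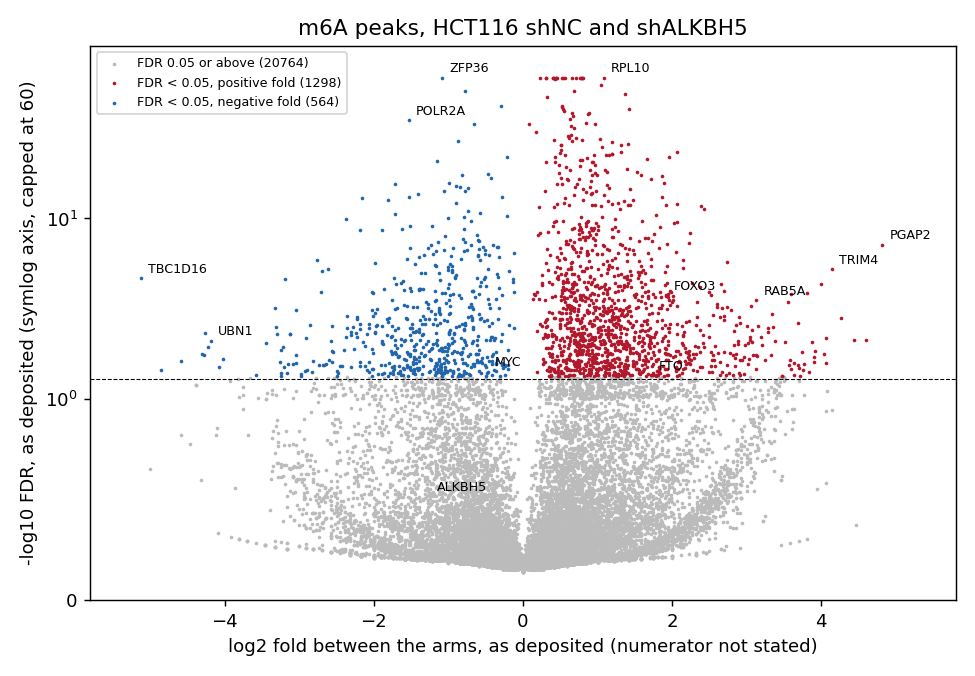
Each point is 1 of the 22626 peaks, with the authors' log2 fold between the arms on the x axis and -log10 of their FDR on the y axis, which is linear below 1 and logarithmic above and is capped at 60. Peaks past an FDR of 0.05 are coloured (1298 positive, 564 negative), and the sign has no stated numerator.

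RAB5A, a GTPase of early endosomes, carried called peaks of both signs. The RAB5A peak at 19983710 to 19984129 on chromosome 3, centred 1255 bases from the annotated 3′ end, had a log2 fold of 3.13 (FDR 0.00031) in the authors' deposited table. The RAB5A peak at 19947396 to 19947605, centred 404 bases from the 5′ end, had -2.60 (FDR 0.024) in the authors' deposited table, and the other 2 RAB5A peaks did not pass. FOXO3, a forkhead transcription factor gene downstream of AKT, had 1 called peak of 3, with a log2 fold of 1.92 (FDR 0.00019) in the authors' deposited table. That FOXO3 peak lies at 108683007 to 108683815 on chromosome 6. MYC had 1 called peak of 3, at -0.47 (FDR 0.041) in the authors' deposited table, which did not pass with p doubled. Neither peak of the Wnt feedback gene AXIN2 passed, with log2 folds of -0.17 and -0.73 in the authors' deposited table.

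**Figure D2:**
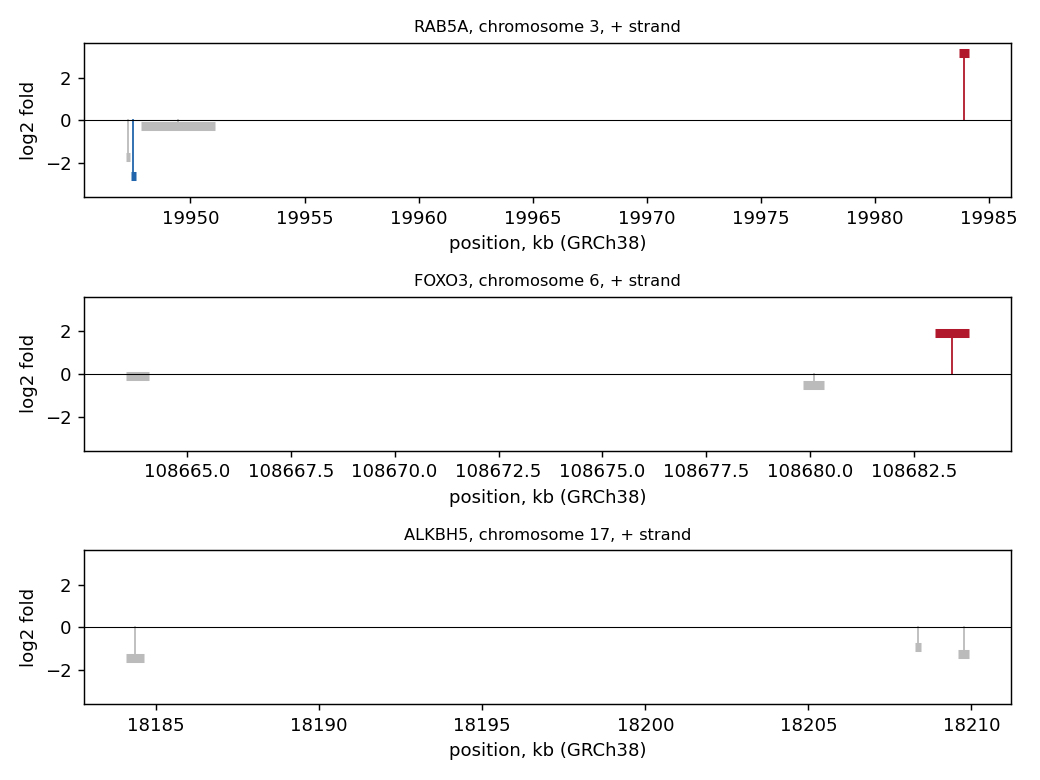
Peaks of RAB5A, FOXO3 and ALKBH5 are drawn from start to end, introns included, along the chromosome in kb (x axis) at the height of the authors' log2 fold (y axis). Red and blue mark positive and negative peaks past an FDR of 0.05, and grey the rest, which holds all 3 ALKBH5 peaks.

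Of the 64 peaks on genes of the m6A machinery 5 were called (7.81%), against 8.23% of all peaks. Of 10 writer genes with a peak, 1 had a positive and 1 a negative called peak. These were, in the authors' deposited table, CBLL1 at 0.90 (FDR 0.03) and ZC3H13 at -1.72 (FDR 0.0079). The other demethylase gene, FTO, had 1 peak, at 1.72 (FDR 0.047) in the authors' deposited table. The CBLL1 and FTO calls were lost with the folds recentred and with p doubled. Of 10 reader genes, 2 had a positive peak, HNRNPA2B1 at 1.92 (FDR 0.025) and HNRNPC at 1.56 (FDR 0.0066) in the authors' deposited table. No peak of METTL3, METTL14, WTAP, YTHDF1, YTHDF2, YTHDF3, YTHDC1 or IGF2BP2 passed, and the smallest FDR among them was 0.085, for YTHDF1, in the authors' deposited table. That YTHDF1 peak, with a negative fold, was called once the folds were recentred. Adjusted over the list alone, the counts of called writer and reader peaks were 1 positive and 1 negative, and 2 positive and 0 negative.

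Mitochondrially encoded transcripts and ribosomal protein genes carried positive-fold peaks more often than other genes. All 12 mitochondrially encoded genes with a peak had a positive called peak, against 9.82% of other genes (Fisher's exact test, two-sided, adjusted p = 2.91e-11 over 34 tests). MT-CO2 reached 0.78 in the authors' deposited table, MT-ND4 0.76, MT-ND5 0.66 and MT-ATP6 0.53. Recentring left 11 of the 12 genes positive and turned 1 negative. With each locus once, 10 of 10 were positive (Fisher's exact test, adjusted p = 2.9e-09), and genes are not independent replicates. Of 44 ribosomal protein genes, 19 had a positive and 3 a negative peak (adjusted p = 1.56e-07 for positive peaks, Fisher's exact test). RPL5 stood at 1.72, RPL37A at 1.16, RPL10 at 1.08 and RPS24 at -1.52 in the authors' deposited table. Recentred, 17 were positive and 3 negative. Histone genes had 12 of 36 members positive and 2 negative (adjusted p = 0.00095, Fisher's exact test), and adjusted p = 0.060 once recentred. In the authors' deposited table, H2AC4 stood at 1.58, H4C8 at 1.16, H2AJ at -1.98 and H2AW at -0.94. The histone count includes the antisense gene H1-10-AS1. Against random lists matched on peak number, peak p and enrichment, the positive calls of all 3 lists did not pass (permutation test, adjusted p = 0.109, 0.17 and 0.25). Adjusted over the list alone, the 3 lists held 15, 22 and 21 positive peaks and 0, 3 and 2 negative ones.

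Genes of epithelial identity carried called peaks of both signs. Of 17 epithelial and mesenchymal genes with a peak, 7 had a positive peak (adjusted p = 0.0050) and 4 a negative one (adjusted p = 0.034), by Fisher's exact test. In the authors' deposited table, the splicing regulator gene ESRP1 stood at 1.45 and the E-cadherin gene CDH1 at 1.15, while the claudin gene CLDN4 stood at -1.41. With p doubled the negative call ended (Fisher's exact test, adjusted p = 0.28), and with an FDR of 0.01 no gene of the list had a negative peak. Against matched random lists neither sign passed (permutation test, adjusted p = 0.17 and 0.43). Of 20 Wnt pathway genes, 6 had a positive and 3 a negative peak (adjusted p = 0.046 for positive ones, Fisher's exact test), where matched lists had 3.56 positive genes on average and the call did not pass (permutation p = 0.23 before adjustment). The authors' deposited table gives 1.22 for CSNK1A1, 1.14 for TCF7L2, 0.95 for the β-catenin gene CTNNB1 and -1.15 for the ubiquitin ligase gene RNF43. Adjusted over the list alone, 10 positive and 6 negative peaks were called in the epithelial list, and 6 and 3 in the Wnt list.

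Glycolysis and stress response genes had positive peaks in 5 of 15 members each (adjusted p = 0.046 for both, Fisher's exact test), and neither list passed once recentred (adjusted p = 0.069) or at an FDR of 0.01 (adjusted p = 0.051). With p doubled the stress response list did not pass either (Fisher's exact test, adjusted p = 0.105). In the authors' deposited table, EPAS1 stood at 1.61, PFKP at 1.41, LDHA at 1.14 and SLC2A1 at 0.63. Of the stress response genes, HERPUD1 stood at 1.07, ASNS at 0.90, HSP90B1 at 0.77 and ATF4 at 0.77 in the authors' deposited table. Adjusted over the list alone, 7 and 8 positive peaks and 1 and 2 negative peaks were called in these lists. Zinc finger genes had a positive peak less often, in 13 of 351 members against 10.1% of other genes (Fisher's exact test, adjusted p = 0.00018). The zinc finger count includes the antisense gene ZNF593OS, called at the locus of ZNF593, and with each locus once it was 12 of 343. The authors' deposited table gives 3.58 for ZNF32, 3.38 for ZNF317, 3.03 for ZNF526 and -3.58 for ZNF18. Adjusted over the list alone, 6 positive and 3 negative zinc finger peaks were called. Against random lists matched on peak number, peak p and enrichment, 0 of the 34 tests passed after adjustment, and zinc finger genes had 13 positive members where matched lists had 14.8 on average. Matching was incomplete for the zinc finger list, where 232 of 349 genes had a higher enrichment than the median of their matched genes (exact sign test, p = 7.4e-10).

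The other lists did not pass in either direction. RAB and endosomal genes had 5 of 19 members positive and 1 negative (Fisher's exact test, adjusted p = 0.115), with TSG101 at 2.09, VPS35 at 1.70 and RAB5C at 0.64 in the authors' deposited table. FOXO and PI3K genes had 2 of 18 positive, FOXO3 and RPTOR, the latter at 1.54 in the authors' deposited table. The p53 list had FDXR at 1.77 and SESN2 at -0.95 in the authors' deposited table, among 14 members. Of 16 cell cycle genes, MCM6 stood at 2.96 and CDK4 at 0.65 in the authors' deposited table. The RPTOR and MCM6 calls were lost with the folds recentred and with p doubled. Apoptosis genes held BID at 1.70, TNFRSF10B at 0.90 and BIRC2 at -1.46 in the authors' deposited table, among 14 members. ISG15, at -0.35 in the authors' deposited table, was the called gene among 17 interferon genes. Among 19 chromatin regulator genes, CREBBP stood at 0.99 and CHD7 at -3.21 in the authors' deposited table. Among markers of other cells, 1 fibroblast gene, 1 leukocyte gene and 0 genes of other lines had a peak, and none was called, although 1 leukocyte peak was positive when adjusted over the list alone. EPCAM, at 0.67 in the authors' deposited table, was the called gene among 3 colorectal epithelium markers with a peak. The EPCAM and CREBBP calls were lost with the folds recentred and with p doubled, and those of TSG101, BIRC2, CHD7, CLDN4 and ZNF18 with p doubled. Adjusted over the list alone, RAB genes had 7 positive and 2 negative peaks and chromatin genes 0 of either sign.

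**Figure D3:**
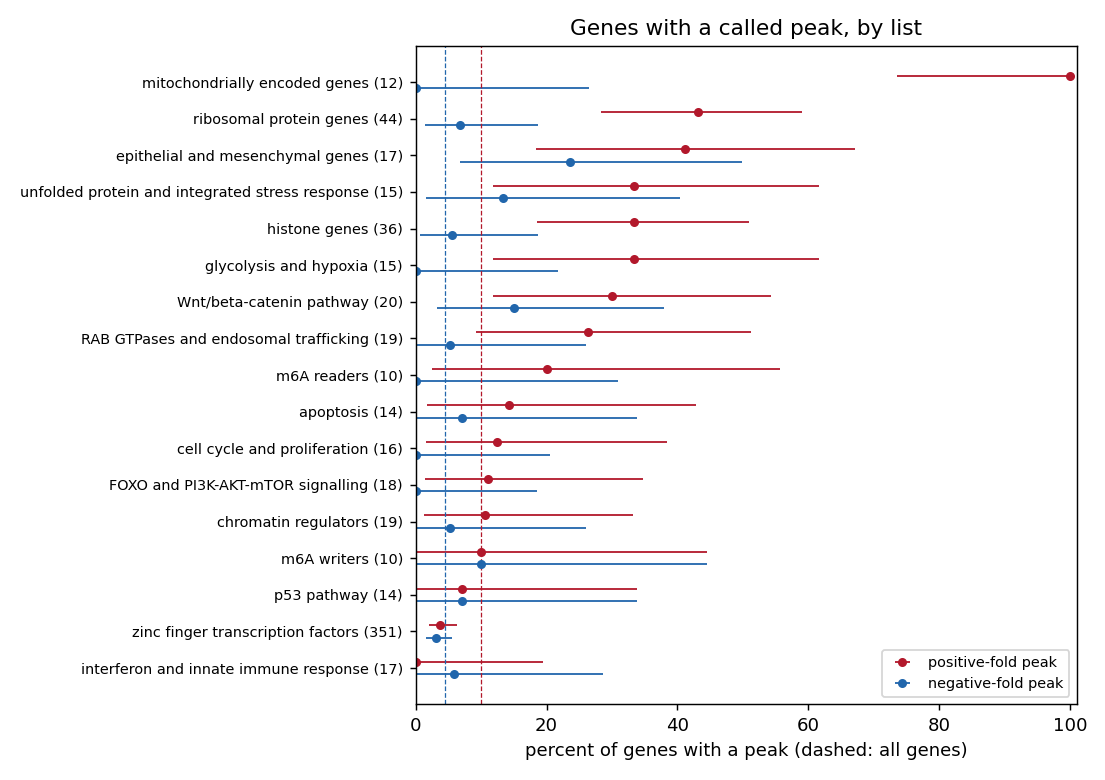
For each list of at least 5 genes with a peak (number in brackets), points give the percent of genes with a called positive (red) or negative (blue) peak, and bars the exact binomial 95% interval. Dashed lines mark all genes with a peak (9.92% positive, 4.49% negative), and mitochondrially encoded genes stand at 100% positive.

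The position of peaks along genes was compared through the annotated 3′ end, since bounds of coding sequence and untranslated regions were not used here. Of 20778 peaks that matched an annotated gene, 4626 (22.3%, exact binomial 95% interval 21.7 to 22.8) were centred within 1000 bases of its 3′ end. Called peaks lay there more often than uncalled ones, at 33.9% against 21.2% (Fisher's exact test, two-sided, p = 1.32e-30). Among called peaks the share was 35.6% for positive and 30.0% for negative folds (Fisher's exact test, p = 0.026). That difference did not pass when each locus was counted once (p = 0.067, Fisher's exact test) or with 1 peak per gene (p = 0.50, Fisher's exact test). It passed with folds recentred, at 38.4% against 30.1% (p = 0.00045, Fisher's exact test), and with p doubled (p = 0.036, Fisher's exact test).

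Positive-fold peaks spanned exon junctions more often than negative-fold ones. The share was 43.7% of 1298 positive, 30.3% of 564 negative and 29.6% of 20764 uncalled peaks, with p = 5.75e-08 for positive against negative (Fisher's exact test, two-sided). Among peaks of at most 400 bases it did not pass, at 32.7% against 28.7% (Fisher's exact test, p = 0.26). In the most significant of 5 classes of peak p, 50.8% of positive and 52.7% of uncalled peaks spanned a junction. TRIM4, NAF1 and BIRC6 are examples among the largest positive folds, each with a peak of 2 exon blocks.

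Called peaks were less enriched than the rest, with a median of 5.93-fold against 10.5-fold (permutation test, two-sided, p = 0.0001, the smallest that 10000 permutations can give). In the authors' deposited table, the called peaks of LDHA (1.27-fold), RPL15 (1.25-fold) and MT-CO2 (1.46-fold) are examples. Among the 4526 peaks with the lowest enrichment, 11.5% had a positive and 3.80% a negative call, and among the 4525 with the highest, 3.62% and 1.57%.

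**Figure D4:**
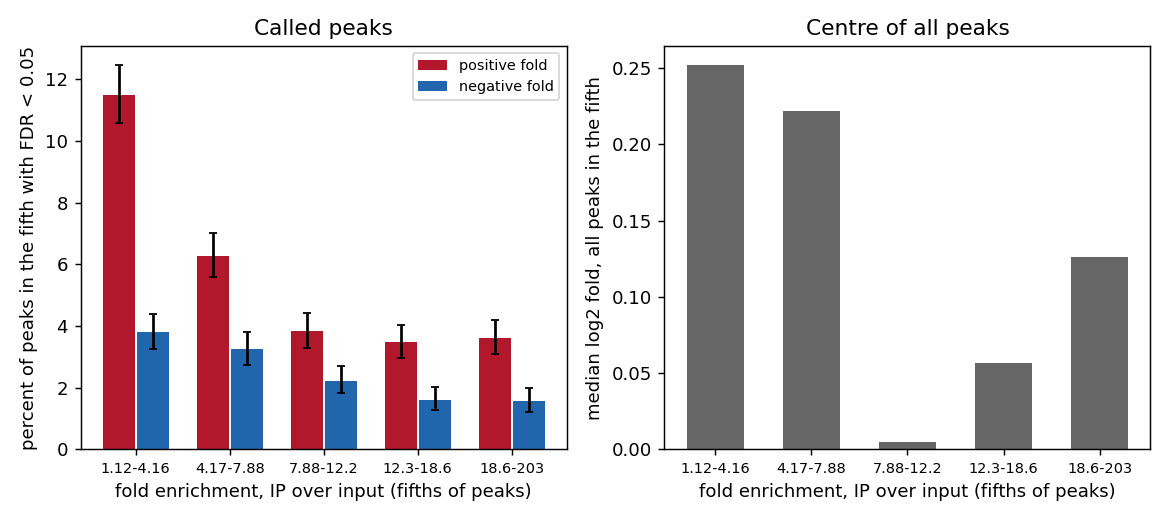
Left, percent of peaks called positive (red) and negative (blue) in each of 5 classes of equal size by the authors' fold enrichment, with exact binomial 95% intervals. Right, median log2 fold of all peaks in each class, which ranges from 0.005 in the middle class to 0.25 in the lowest.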

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

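All alternatives with loci, unadjusted or doubled p, enrichment, gene class, windows in bases, recentring or matched lists, and those for junctions, were chosen after seeing the data. No paired analysis was possible because the table holds no values per library. For the same reason leaving out replicates, other normalizations, tools, filters and pseudocounts, the level of ALKBH5, enrichment within each arm, overlap of peak sets and the relation to expression were not run. Motif alternatives were not run without a genome. The depth of the libraries is unknown, so what it limits could not be assessed.

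The count of called peaks, 1862, was 1121 at an FDR of 0.01 (816 positive, 305 negative), 1058 with an absolute log2 fold of at least 1 (711 and 347), 594 among peaks at or above the median enrichment (404 and 190) and 4493 at an unadjusted p of 0.05 (2910 and 1583). Stricter thresholds and fewer peaks lower these counts by construction. Recentring kept 934 of the 1298 positive calls and all 564 negative ones, and added 263 negative ones.

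The percent positive, 69.7%, was 72.8% at an FDR of 0.01, 67.2% with an absolute log2 fold of at least 1, 64.8% at an unadjusted p of 0.05, 67.3% in nuclear protein-coding genes without ribosomal protein genes, 72.0% with p doubled and 53.04% with folds recentred. The share within 1000 bases of the 3′ end, 22.3%, was 16.8% by the 5′ edge of peaks, 25.9% by the 3′ edge, 24.4% for the more significant peaks, 28.2% with 1 peak per gene, 21.7% with each locus once, 12.6% within 500 bases and 35.9% within 2000. The odds ratio of positive against negative peaks there, 1.29, no longer passed by the 5′ edge (1.23), the 3′ edge (1.22), with 1 peak per gene (1.10), within 2000 bases (1.23) or with each locus once (1.24), and the cause was not tested. That odds ratio still passed for the more significant peaks (1.27), within 500 bases (1.31), with p doubled (1.32) and with folds recentred (1.45). The 9 list tests that passed became 0 against matched random lists. In 49 alternatives the results kept their direction and side of the threshold, or stayed within 1.5 times a count or within the interval of a share. A further 15 were weaker, 3 were stronger and 13 gave a share outside its interval. The 49 include the recentred counts of 934 positive and 827 negative peaks, although the share these give lay outside its interval. The higher share of junctions in positive than negative peaks did not pass among peaks of at most 400 bases (Fisher's exact test, p = 0.26).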

Other observations

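The tests of weak enrichment, of recentring, of how well the lists were matched, of signs within genes, of the middle class of enrichment, of the demethylase and of peak length were chosen only after the result was seen. The genes of this paragraph were picked after their values were seen. The authors' deposited table gives a log2 fold of -1.09 for ZFP36, whose protein destabilises AU-rich messages, -0.78 for S100A6, -1.53 for the RNA polymerase II gene POLR2A and -0.30 for the nuclear RNA MALAT1. Positive folds were 0.79 and 0.81 at separate peaks of the cadherin gene FAT1, 0.71 for AKAP12, 1.37 for the small nucleolar RNA host ZFAS1 and 0.52 for PTMA in the authors' deposited table. None of the 23 peaks of AHNAK2 was called, while 4 of the 14 peaks of EPPK1 were, all with negative folds, in overlapping pairs at 2 loci.

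Folds of neighbouring peaks of a gene were weakly correlated. Across 10617 neighbouring pairs Spearman's rho was 0.066 (Pearson's r = 0.068, permutation p = 0.0001, the smallest that 10000 permutations can give), and peaks are not independent replicates. Peaks of a gene that overlap each other (198 pairs) were not removed, and how much of the correlation they carry was not tested. Of 186 genes with at least 2 called peaks, 102 had positive, 34 negative and 50 both signs. With signs shuffled over these called peaks, 86.0 genes on average held both (permutation test, two-sided, p = 0.0002, the smallest these permutations can give), and 79.1 with overlapping peaks of a gene counted once, where 50 still did.

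Positive folds made up 69.7% of called peaks. Background reads in weakly enriched transcripts would remove the excess at high enrichment, yet it was 69.8% in the 4525 peaks with the highest enrichment (exact interval 63.5 to 75.6), and counting each locus once gave 69.6%. A uniform shift between the arms stays open for part of it, since recentring left 53.04% (exact interval 50.7 to 55.4, and 48.0 to 58.5 with chromosomes resampled) and 54.6% with predicted standard errors alone (exact interval 52.1 to 57.1), but 63.1% (exact interval 57.1 to 68.9) were positive in the middle one of 5 classes of enrichment, where the median fold was already 0.005. The medians of the classes, from 0.005 to 0.25, are not 1 common shift, and recentring does not separate scaling from a change of m6A at most sites. Loss of the demethylase cannot be told apart from these, because the numerator behind the 69.7% is not stated.

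Mitochondrially encoded and ribosomal protein genes carried positive peaks at low enrichment, with medians of 2.73-fold and 3.30-fold. A candidate explanation is their abundance, which lets small folds pass. Random lists matched on peak number, peak p and enrichment had 7.27 positive genes on average against 12 (two-sided permutation p = 0.0032) and 12.3 against 19 (two-sided permutation p = 0.015), but adjusted over all 34 tests neither passed (adjusted permutation p = 0.109 and 0.17). Abundance cannot be told apart from other causes for either list, because the matching was incomplete: all 12 mitochondrially encoded genes had a smaller peak p than the median of their matched genes, and only 10 of 44 ribosomal protein genes had a higher enrichment than theirs (exact sign test, p = 0.00049 and 0.00039), although their peak p was balanced (22 of 44). Pseudogene peaks of any gene made up 7.24% of positive (exact interval 5.9 to 8.8), 1.60% of negative (0.7 to 3.0) and 3.41% of uncalled peaks (3.2 to 3.7). Whether reads were shared with nuclear copies and pseudogenes was not tested, and no biological explanation was tested.

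Positive peaks spanned exon junctions more often than negative ones, and no biological explanation was tested. Positive peaks were not the longer ones, with a median exonic length of 391 bases against 449 for negative peaks. Against length as the whole cause, among peaks of over 400 bases 55.1% of positive and 31.6% of negative ones spanned a junction (Fisher's exact test, p = 9.16e-12), although among shorter ones 32.7% and 28.7% did (Fisher's exact test, p = 0.26). The difference stood with each locus once (Fisher's exact test, p = 1.08e-07) and in the most significant of 5 classes of peak p (Fisher's exact test, p = 6.95e-06). In that class, positive peaks (50.8%) did not exceed uncalled ones (52.7%), so there the negative peaks stand apart.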
